A study of Homo sapiens with 8 samples.

How the data were processed

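RNA-seq was made from leukemia stem cells of 4 leukapheresis specimens, each with a vehicle and a STAT3i library, 8 libraries in all. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with SMARTer amplification and Nextera XT for low input. Amplification by PCR without molecular identifiers means that reads are not independent molecules, so limits from read counts cover counting error only. Per the submitters' processing notes, bcl2fastq 2.19.0, Trimmomatic 0.36, STAR 2.6.0c, DESeq2 1.16.1 and R 3.4.1 were used with build hg38. The read counter, the gene annotation and the use of strand are not given in the sources used here. The deposited values are a signal, gene read counts that the authors divided by a DESeq2 size factor for each library, with 1 column per library and no pooling.

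Each library's values were whole multiples of its smallest positive value. Dividing by that step gave whole reads within 0.001 for 100% of positive values, with a largest deviation of 0.000288. A count of 3 reads corresponds to between 1.757 and 3.784 normalized counts, depending on the library. The table had 56870 rows, of which 24034 had no read in any library. In 28 rows a date stood in place of the gene symbol, and these rows, with 0.245% of the reads, were left out of the tests. Some genes were listed at or near 0 though others of their pathway were abundant, among them IL3RA at 0 in 8 libraries, ASNS and NOP2, so a low value need not mean low expression. BEST1 had between 0.822 and 0.871 times the value of FTH1, a gene it overlaps, in every library, and such genes cannot be told apart here.

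Values were analysed as log2(value + 1), so a fold change is on that scale and understates the change of low genes. Genes with at least 10 normalized counts in at least 4 libraries were kept. The main test was limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance, donor and treatment as terms, and Benjamini-Hochberg adjustment over 14504 genes at 0.05. Donor was a term because the labels give each specimen both treatments. This departs from a default of leaving the block out where no methods text asks for it. The choice was made before the data were examined, and the fit without the donor term is reported beside it. The check of the pairing gave correlations of the deviations from the group means of 0.883, 0.919, 0.909 and 0.881 for libraries of the same donor, and at most -0.125 between donors. Gene lists were tested with camera at a preset correlation of 0.01, over the 34 of 41 lists with at least 5 measured members. Lists with fewer were left out of the tests. Alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, other pseudocounts (0.5 and 5), filters and scalings, array weights, camera with an estimated correlation, fry, and each donor left out in turn, with the filter applied again to the 6 remaining libraries. Correction for GC content and transcript length by natural splines with 4 degrees of freedom, the annotated genes alone, and thinning to 8567092 reads were added after seeing the data. Symbols were matched to GENCODE release 29, by current symbol for 29497 and by older symbols for 984 of 56868 distinct symbols, and 84.1% of tested genes and 95.3% of called genes had an annotated transcript.

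Genes were named by a fixed rule: the 3 genes of the series title, then the 12 largest rises and 12 largest falls among called genes that moved the same way in 4 donors with a mean of at least 50, then up to 4 members of each described list by smallest p. Genes of the Y chromosome, XIST and TSIX, commonly deleted genes, immune receptor segments and clone identifiers were not named. CYP1B1, TIPARP, AHRR, ABCA1, SCD, MAT2A, BEST1, IL3RA, ASNS and NOP2 were chosen after their values were seen. Results for 2 genes that the rule takes are not reported here. On simulated reads with the real means, dispersions and donor structure (14214 genes, 200 changed), the test of STAT3i against vehicle recovered 50.7% of genes with a fold of 1.5, 68.7% at a fold of 2 and 90.9% at a fold of 3, with 5 calls among unchanged genes. In 20 simulations with no change, at most 2 genes were called, and at most 1 list, for genes simulated as independent.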

Results

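RNA was sequenced from leukemia stem cells, the fraction of acute myeloid leukemia cells thought to sustain the disease, isolated from leukapheresis specimens and kept in culture medium. Cells of 4 specimens, taken as 4 donors and named A to D here, were each exposed to DMSO vehicle or to an inhibitor of the transcription factor STAT3, written STAT3i, which gave 8 libraries with n = 4 per group. The identity of the inhibitor, its dose and the time of exposure are not given in the sources used here. Recovered reads per library ranged from 8567092 to 18880304, with a mean of 10920000 ± 815000 (SD, n = 4) for vehicle and 12770000 ± 4630000 (SD, n = 4) for STAT3i. The highest depth was that of the STAT3i library of donor A. The share of reads from mitochondrial DNA was 2.574% ± 1.12 (SD, n = 4) with vehicle and 3.327% ± 1.4 (SD, n = 4) with STAT3i and was higher with STAT3i in 4 of 4 donors, for which the exact two-sided sign-flip test gave p = 0.125, the smallest value that 4 pairs allow. Donors differed far more than treatments. The first 3 principal components, with 43.684%, 27.091% and 21.503% of the variance, separated donors, and the fourth, with 2.954%, separated vehicle from STAT3i in 4 of 4 donors.

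The comparison of STAT3i with vehicle addresses how STAT3 inhibition alters expression of MYC, of the glutamine transporter gene SLC1A5 and of genes for oxidative phosphorylation, the subjects named in the title of the series. SLC1A5 fell in 4 of 4 donors. STAT3 and MYC did not pass the test. SLC1A5 (ENSG00000105281, chromosome 19, 46774883 to 46788594, minus strand) had 1841 ± 1248 normalized counts with vehicle and 1301 ± 891.8 with STAT3i (SD, n = 4). Its log2 fold change was -0.51 ± 0.08 (SE), a fold of 0.703 with a 95% interval of 0.62 to 0.8, with limma adjusted p = 0.02004, and the donor differences lay between -0.54 and -0.48. MYC, a transcription factor that drives growth and biosynthesis (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand), had 1245 ± 493.3 normalized counts with vehicle and 676.6 ± 277.1 with STAT3i (SD, n = 4). Its log2 fold change was -0.87 ± 0.20 (SE), with limma adjusted p = 0.05003, which misses the threshold of 0.05. The MYC difference was -1.51 in donor A, -1.26 in donor C, -0.74 in donor D and 0.03 in donor B. The call of MYC turned on the method, with adjusted p = 0.0397 by edgeR, 0.00318 by DESeq2 and 0.029 by limma without donor B. By limma MYC was not called without donor A (adjusted p = 0.193), C (0.0714) or D (0.195). Nor was it called with no filter (0.117), a pseudocount of 0.5 (0.0665) or GC and length corrected (0.0806). STAT3 itself (ENSG00000168610, chromosome 17, 42313324 to 42388568, minus strand) had 4155 ± 427 normalized counts with vehicle and 4256 ± 547 with STAT3i (SD, n = 4), a log2 difference of 0.03 ± 0.08 (SE) with limma adjusted p = 0.8677. The 95% interval of the STAT3 log2 difference was -0.15 to 0.22. Coordinates are those of GENCODE release 29 on GRCh38, and each value covers the whole gene. The SLC1A5 call was lost when donor A (adjusted p = 0.0803), donor B (0.0684) or donor D (0.0686) was left out, with a log2 fold change between -0.52 and -0.50 over the 4 omissions. Exons of SLC1A5 overlap an annotated gene on the opposite strand, whose reads cannot be told apart if strand was not used in counting.

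**Figure D1:**
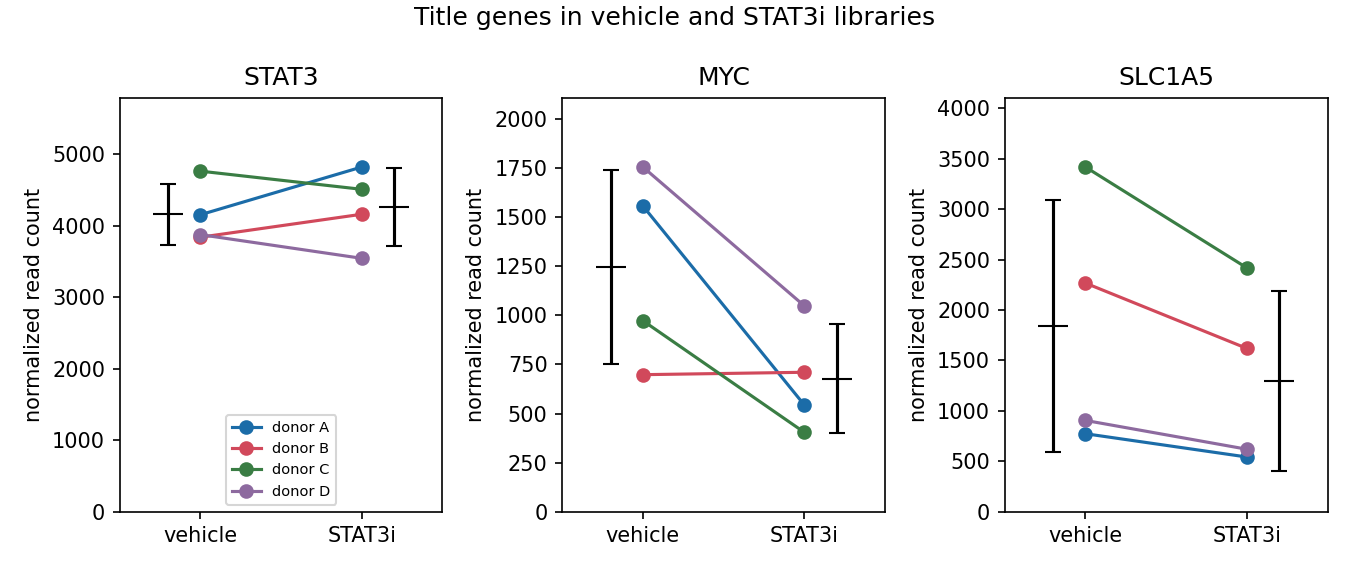
Normalized read counts (vertical axes, from 0) of STAT3, MYC and SLC1A5 in vehicle and STAT3i libraries, with a line for each of 4 donors and black bars for the mean ± SD of 4 libraries. SLC1A5 is lower with STAT3i in 4 of 4 donors, MYC lies between 697.9 and 710.1 in both libraries of donor B, and STAT3 moves in both directions.

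Across the transcriptome, 408 of 14504 tested genes changed with STAT3i, 219 higher and 189 lower, and 408 of the 408 moved the same way in all 4 donors. The paired test favours genes whose donors agree, so this follows largely from the selection. Of all tested genes, 28.2% moved the same way in 4 donors, against 12.5% expected by chance. At a fold of 2 or more, 17 genes rose and 29 fell. The genes with the largest rises included the guidance and growth factor receptor NRP2, the nuclear receptor NR4A3 and hepatocyte growth factor, HGF. NRP2 had 96.1 ± 115.2 normalized counts with vehicle and 215.6 ± 234.8 with STAT3i (SD, n = 4), with a log2 fold change of 1.57 ± 0.29 (SE) and limma adjusted p = 0.02795. Its reads with vehicle and STAT3i were few in donor A (1 and 13) and donor B (5 and 19). The log2 fold change was 1.52 for NR4A3 and 1.51 for HGF. The HGF call was lost in 11 of 17 alternatives, among them the pseudocount of 0.5 (1.74, adjusted p = 0.083), DESeq2 (1.30, 0.146) and the omission of donor A (0.103), B (0.155) or D (0.1). Donor C had 0 HGF reads with vehicle and 6 with STAT3i, and without this donor the log2 fold change was 1.03 (adjusted p = 0.0294). The secreted phosphoprotein SPP1 rose by 1.27, the cytokine TNFSF14 by 1.17, and the chemokines CCL3 and CCL4 by 1.11 and 1.09 on the log2 scale. ABTB2, ZC3H12C, MFSD2A, AP1S3 and ZNF165 completed the 12 largest rises, with log2 fold changes from 1.13 to 1.37. CCL3 and CCL4 have near-identical copies in the genome, so their counts are uncertain. The largest fall was that of CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, at -2.69 ± 0.41 (SE, limma adjusted p = 0.01758), from 104.6 ± 118 to 9.93 ± 10.7 normalized counts (SD, n = 4). CYP1A1 reads with vehicle and STAT3i were 256 and 41 in donor A and 163 and 10 in donor D. They were few in donor B (5 and 1) and donor C (13 and 2). The myeloid surface receptor CD33 fell to a fold of 0.417 and the myeloid transcription factor CEBPA to a fold of 0.447. CEBPA lost its call in 7 of 17 alternatives, and its donor differences ran from -0.115 in donor C to -2.165 in donor D. MPZL2 fell by 2.10, FUT7 by 1.76, ZBED6CL by 1.39, ACADSB by 1.30, TMEM14A by 1.18 and UMODL1 by 1.18. XAF1 and IFIT1, both interferon-stimulated, fell by 1.24 and 1.21. FUT7 shares exon sequence with another gene on its own strand, and NRP2, ZNF165, CCL3, XAF1, UMODL1 and CEBPA do so with genes on the opposite strand. The count rests on the pairing, since limma without the donor term called 0 genes, with 122 at an unadjusted p under 0.05, while edgeR and DESeq2 with the donor term called 433 and 959. It was 8 without donor A, 44 without donor B, 67 without donor D and 752 without donor C, where the filter was applied again to the 6 remaining libraries and left 13713 to 13762 genes. On the 14504 genes tested with all donors, an alternative chosen after seeing the data, it was 8, 41, 53 and 730 without donors A, B, D and C. Of the 24 largest rises and falls, 22 lost their call without donor A, 16 without donor B, 14 without donor D and 3 without donor C. CYP1A1 did not pass the filter without donor A or D, nor NRP2 without donor C or D, so they were not tested there. Where NRP2 was tested, without donor A or B, its call was lost (limma adjusted p of 0.0752 to 0.0796). NR4A3 and ZC3H12C passed under no omission, with limma adjusted p of 0.0657 to 0.113 and 0.0844 to 0.1. ZC3H12C had 0 reads with vehicle and 3 with STAT3i in donor B, and lost its call in 7 of 17 alternatives. With a pseudocount of 0.5, 6 of the 24 lost their call.

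The list of interferon-stimulated genes was lower and that of TNF and NF-kB response genes higher at the preset correlation, and neither passed with an estimated correlation. Of 27 interferon-stimulated genes, 14 fell, 0 rose and 13 did not pass, with a median log2 fold change of -0.64, and 17 fell when adjusted over the list alone. The antiviral gene RSAD2 fell by 0.97 ± 0.18 (SE, limma adjusted p = 0.0289), a call lost without donor A (adjusted p = 0.126), B (0.0942) or D (0.0797). The camera adjusted p of the list was 3.49e-10 with the preset correlation, and adjusted p = 0.696 with an estimated correlation. Of 25 TNF and NF-kB response genes, 12 rose, 0 fell and 13 did not pass, with a median of 0.59, and 17 rose when adjusted over the list alone. NFKBIA, the inhibitor that NF-kB induces against itself, rose by 0.74 ± 0.07 (SE, limma adjusted p = 0.00924). The feedback deubiquitinase TNFAIP3 rose by 0.88, TRAF1 by 0.80 and the NF-kB subunit RELB by 0.64. The camera adjusted p of this list was 7.86e-09, and adjusted p = 0.646 with an estimated correlation. Of 20 immediate early genes, 2 rose, JUNB by 0.61 and ZFP36 by 0.54, and 4 rose and 1 fell when adjusted over the list alone. The median was 0.21 with camera adjusted p = 0.0217, and adjusted p = 0.696 with an estimated correlation. Immediate early genes lost their call as a list without donor B, at a median of 0.11 and adjusted p = 0.275, without the donor term (0.425) and after quantile normalization (0.0542). Of 32 genes of the STAT3 pathway, 3 rose and 1 fell, and 9 rose and 4 fell when adjusted over the list alone, with a median of 0.02 and camera adjusted p = 0.533. The fry test for changes in either direction gave adjusted p = 0.00182 for this list. That test asks whether members changed at all, not whether they changed more than other genes. Of the 34 tested lists 14 passed it, and 3047 of 14504 genes had an unadjusted limma p under 0.05. Of the STAT3 pathway genes, NFKBIZ (0.81), ICAM1 (0.71) and JUNB (0.61) rose, and the cyclin CCND3 fell by 0.60. ICAM1 is also in the NF-kB list and JUNB in the immediate early list. NFKBIA and TNFAIP3 passed under each omission of a donor. TRAF1 lost its call without donor A (adjusted p = 0.057), as did RELB (0.0782), NFKBIZ (0.0637) and ICAM1 (0.0792), which lost theirs without donor B too (0.0509, 0.0509 and 0.0576). JUNB and ZFP36 lost theirs without donor A (0.149 and 0.155), B (0.119 and 0.132) or D (0.0584 and 0.0912), and CCND3 without donor A (0.139), C (0.0561) or D (0.157).

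At the preset correlation, respiratory chain subunits encoded by mitochondrial DNA passed as a list with a higher median, nuclear genes for complex I passed with a lower one, and nuclear genes for complexes II to V did not pass. None passed with an estimated correlation or by fry. The difference between the 2 genomes was not tested. Of 36 nuclear genes for complex I, 33 had lower and 3 higher values, 0 passed the limma test alone or when adjusted over the list alone, and the median was -0.17 with camera adjusted p = 0.000447. That call was lost with adjusted p = 0.848 with an estimated correlation and without donor B, at a median of -0.12 and 0.0872. Donor medians of complex I were -0.11, -0.39, 0.03 and -0.27, and of complexes II to V 0.04, -0.33, 0.17 and -0.25, for donors A to D. The smallest p belonged to NDUFS5, with a log2 difference of -0.38 ± 0.12 (SE, limma adjusted p = 0.104). Of 40 nuclear genes for complexes II to V, 0 passed, 0 when adjusted over the list alone, and the median was -0.09 with camera adjusted p = 0.0986. This list passed without the donor term (adjusted p = 0.0353), without a filter (0.037), after quantile normalization (0.00186), without donor A (0.0142) and without donor C (0.000816). The 13 subunits encoded by mitochondrial DNA had a median of 0.35 with camera adjusted p = 5.18e-06, and adjusted p = 0.696 with an estimated correlation. Of these 3 rose, MT-CO1 by 0.50 ± 0.08 (SE), MT-ND4 by 0.42 and MT-ND2 by 0.44, and 12 rose when adjusted over the list alone. The calls were lost in 5 of 17 alternatives for MT-CO1, 7 for MT-ND4 and 8 for MT-ND2. MT-ND4 and MT-ND2 passed under no omission of a donor (adjusted p = 0.0516 to 0.154 and 0.0547 to 0.158), and MT-CO1 did not without donor A (0.0637), B (0.0633) or D (0.0795). The share of all reads from mitochondrial DNA, higher with STAT3i in 4 of 4 donors, includes the reads of these 13 genes and is not separate evidence. Of 74 mitochondrial ribosomal protein genes, 1 fell, MRPL40 by 0.81 ± 0.13 (SE), as also when adjusted over the list alone, with a median of -0.16, camera adjusted p = 0.000436 and adjusted p = 0.696 with an estimated correlation. The MRPL40 call was lost without donor A (0.0937), B (0.0692) or D (0.0713). Of 78 cytosolic ribosomal protein genes, 0 passed, 0 when adjusted over the list alone, and the median was 0.22 with camera adjusted p = 1.74e-06, and adjusted p = 0.852 with an estimated correlation. The donor medians of that list were 0.41, -0.10, 0.54 and -0.03. Cytosolic ribosomal proteins had a median of 0.145 without donor A (camera adjusted p = 0.00179) and 0.11 without donor C (0.0351).

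Lists of MYC targets, amino acid metabolism, cholesterol synthesis, fatty acid oxidation and S phase were lower at the preset correlation, and none of them passed with an estimated correlation. Of 58 MYC targets, 3 fell, the folate carrier SLC19A1 by 0.80, CAD of pyrimidine synthesis by 0.53 and DCTPP1 by 0.48, and 13 fell and 2 rose when adjusted over the list alone. The median was -0.19, negative in 4 of 4 donors, with camera adjusted p = 7.08e-05. The adjusted p was 0.0271 by fry, and adjusted p = 0.547 with an estimated correlation. Of 25 genes of amino acid and glutamine transport and metabolism, 4 fell, and 5 fell and 1 rose when adjusted over the list alone. They were SLC1A5, the serine synthesis enzyme PHGDH (0.72), the transporter SLC7A5 (0.54) and ALDH18A1 of proline synthesis (0.47). The median was -0.14 with camera adjusted p = 0.0209, adjusted p = 0.696 with an estimated correlation, 0.344 without donor C (median -0.09) and 0.122 without the donor term. Of 21 cholesterol synthesis genes, 5 fell, and 9 when adjusted over the list alone, with a median of -0.42, camera adjusted p = 1.39e-06 and adjusted p = 0.696 with an estimated correlation. Without donor C, whose median was -0.85, the median of the list was -0.20 (camera adjusted p = 0.000816). Among the genes that fell, LSS fell by 0.61, DHCR7 by 0.79 and HMGCS1 by 0.65. Of 20 fatty acid oxidation genes, 2 fell, DECR1 by 0.51 and FABP5 by 0.80, and 4 when adjusted over the list alone, with a median of -0.23, camera adjusted p = 0.000321 and adjusted p = 0.625 with an estimated correlation. Of 30 S phase genes, 1 fell, UHRF1 by 0.70, and 8 when adjusted over the list alone, with a median of -0.37, camera adjusted p = 2.86e-06 and adjusted p = 0.696 with an estimated correlation. The UHRF1 call was lost in 9 of 17 alternatives and under every omission of a donor (0.0512 to 0.167). Under every omission the calls of SLC19A1 (0.0529 to 0.139, and in 7 of 17 alternatives), SLC7A5 (0.0554 to 0.129) and DHCR7 (0.0591 to 0.107) were lost too. Without donor A, B or D they were lost for CAD (0.134 to 0.173), DCTPP1 (0.109 to 0.159), PHGDH (0.0584 to 0.0822), ALDH18A1 (0.0833 to 0.151), LSS (0.0797 to 0.101), HMGCS1 (0.0897 to 0.107), DECR1 (0.109 to 0.154) and FABP5 (0.0968 to 0.151), and for SLC1A5 as given above. CAD also lost its call in 7 of 17 alternatives and DCTPP1 in 5. The 27 mitosis genes had a median of -0.02 with camera adjusted p = 0.61, 13 higher and 14 lower, and 0 passed. Those with the smallest p were TOP2A (-0.63, limma adjusted p = 0.117), KIF23 (-0.79, 0.157), MKI67 (-0.93, 0.161) and CDC20 (-0.74, 0.228). In all, 12 of 34 lists passed with the preset correlation, 4 higher and 8 lower, 1 by fry and 0 with an estimated correlation, and 14 passed the fry test for changes in either direction. Exchanging the treatments within donor pairs called up to 11 lists at the preset correlation. Such exchanges leave some donors in the real direction, so they are not free of the treatment.

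**Figure D2:**
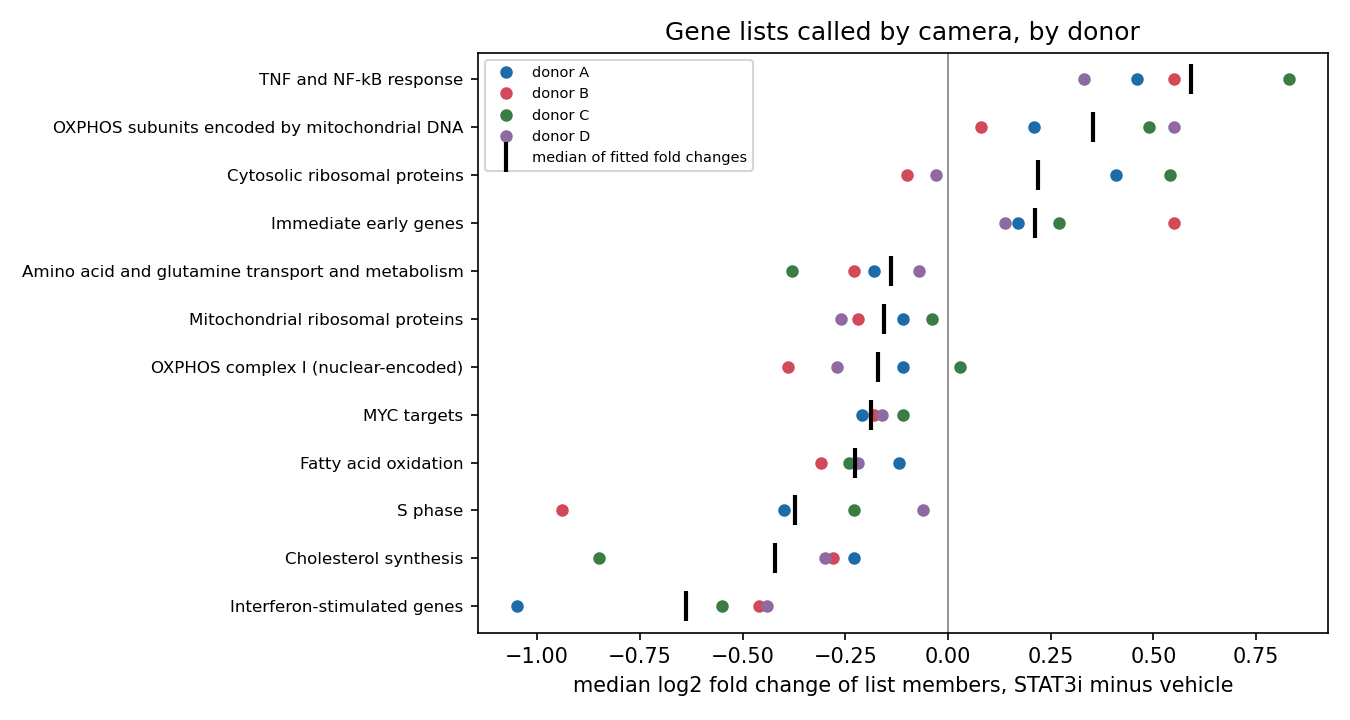
Median log2 fold change, STAT3i minus vehicle, of the 12 gene lists that passed camera with the preset correlation, with a point for each of 4 donors and a black mark for the median of fitted fold changes. The interferon-stimulated list is below 0 and the NF-kB list above 0 in 4 of 4 donors, while cytosolic ribosomal proteins lie on both sides of 0.

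Markers of other cell types did not pass as lists with all 4 donors. Monocyte markers passed in 1 of 16 alternatives, without donor D, at a median of -0.87 (camera adjusted p = 0.00113 at the preset correlation). The filter was applied again there, which can change the members of the list. The median log2 difference was -0.21 for 10 monocyte markers (camera adjusted p = 0.422, donor medians -0.51, 0.03, -0.71 and 0.18), -0.16 for 14 T cell markers (0.282), -0.06 for 8 NK cell markers (0.675), -0.004 for 7 megakaryocyte and platelet markers (0.997) and -0.17 for 5 mast cell and basophil markers (0.772). The 24 myeloid differentiation markers had a median of -0.10 (0.422), and 3 of them changed, CD33 and S100A9 (fell by 0.84) lower and MPO 0.42 higher. The 18 stem and progenitor markers had a median of -0.09 (0.997), with PBX3 0.74 higher, and the 17 genes of the LSC17 stemness score a median of 0.03 (0.901), with ADGRG1 0.52 higher. The MPO call was lost under every omission of a donor (0.0514 to 0.186). That of CD33 was lost without donor A (0.0961) or B (0.0518), that of PBX3 without donor A, B or C (0.059 to 0.172), and those of S100A9 (0.0822 to 0.154) and ADGRG1 (0.0902 to 0.133) without donor A, B or D. Medians of the other tested lists were -0.05 for the TCA cycle (camera adjusted p = 0.61), -0.04 for glycolysis (0.808), -0.09 for the integrated stress response (0.772) and 0.11 for the unfolded protein response (0.422). They were -0.05 for NRF2 targets (0.88), 0.05 for heat shock (0.425), -0.02 for p53 targets (0.88), 0.17 for survival members of the BCL2 family (0.422) and -0.08 for its pro-apoptotic members (0.864). Hypoxia genes had a median of 0.11 (0.604) and autophagy and lysosome genes 0.05 (0.433). PPP1R15A of the integrated stress response rose by 0.51 (limma adjusted p = 0.0247) and DNAJB9 of the unfolded protein response by 0.60 (0.0348). SQSTM1, in the NRF2 and autophagy lists, rose by 0.56 (0.0279). How the calls of PPP1R15A, DNAJB9 and SQSTM1 fare with a donor left out is not reported here. The fry test for either direction gave adjusted p = 0.00206 for the integrated stress response and 0.0191 for the unfolded protein response. It gave 0.0266 for autophagy and 0.0312 for p53 targets. As for the STAT3 pathway list, this test does not compare a list with other genes.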

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

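The tests of the monocyte share and of cycling cells were chosen after the values they use had been seen, as were the GC and length correction and the thinning as settings. An explanation was set aside only where the whole 95% interval cleared its bound and 4 of 4 donors shared the sign, a requirement added after a first calculation without it. The share of monocytes was held to the interval alone. The 95% intervals of list medians and locations were taken over the genes of a list, as if independent. They do not measure the spread between donors. In groups of 4 donors or libraries, 7 of 132 values had one member far from the others, against 6.6 expected by chance at 1 in 20. The gap was 0.932 of the range for NDUFB10 and 0.938 for PHGDH, both lowest in donor B. It was 0.839 for DHCR7, 0.876 for HMGCS1 and 0.888 for the cholesterol synthesis list median, with donor C lowest. For the mitosis list median it was 0.845, with donor C at -0.44 and the others near 0. For stem and progenitor markers it was 0.871, with donor D at -0.25 and the others above 0.

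The median of interferon-stimulated genes was below 0 and that of NF-kB response genes above 0 in 4 of 4 donors. Neither list passed with an estimated correlation (adjusted p = 0.696 and 0.646) or by fry (0.152 for both). A trend with GC content and transcript length as the whole cause is argued against, since after its removal the smaller absolute list median was 0.596 and both lists passed camera at the preset correlation. Unequal depth is argued against by thinning, after which it was 0.6. A higher share of monocytes would need their markers to reach the NF-kB median of 0.59, and the upper 95% limit of their location was 0.193. Several of these markers, CSF1R and FCGR3A among them, are also in the list of myeloid differentiation markers. A fall within the leukemia cells could hide a change in share, so the share is not settled by them. These markers were not steady. Without donor D, the only 1 of 16 alternatives in which they passed, their median was -0.87 (camera adjusted p = 0.00113), in the direction of a lower share. The donor medians of the markers were -0.51, 0.03, -0.71 and 0.18, below those of the NF-kB list in the same donors, 0.46, 0.55, 0.83 and 0.33. Whether the inhibitor acts on these genes through STAT3 or in another way was not tested.

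Nuclear genes for complex I and mitochondrial ribosomal proteins were lower while mitochondrially encoded subunits were higher. Removal of the GC and length trend left medians of -0.116 for complex I and -0.103 for the mitochondrial ribosome, with 95% intervals of -0.166 to -0.079 and -0.149 to -0.045, which reach past the bound of -0.1 set beforehand. Both lists still passed camera at the preset correlation after it, with adjusted p = 0.00259 and 0.00662. Before it neither passed with an estimated correlation (0.848 and 0.696), and complex I did not pass without donor B (0.0872). After the correction both intervals over genes excluded 0 and both medians were negative in 4 of 4 donors, though near 0 in donor C. For donors A to D they were -0.06, -0.24, -0.02 and -0.15 for complex I. For the mitochondrial ribosome they were -0.07, -0.13, -0.02 and -0.16. Before the correction the complex I median of donor C was 0.03. The trend may explain part of the lower values, and whether it explains all of them is left open at that bound. Scaling did not account for the whole mitochondrially encoded rise, whose median was 0.345 under TMM scaling and 0.297 after quantile normalization. TMM scaling moved the median of all genes by only -0.009, so it could remove little. After quantile normalization the donor medians were 0.08, 0.03, 0.28 and 0.54, against 0.21, 0.08, 0.49 and 0.55 before. This list too did not pass with an estimated correlation (adjusted p = 0.696) or by fry (0.233). No biological explanation was tested.

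S phase genes were lower as a list, though 1 of 30 passed and the list did not pass with an estimated correlation (adjusted p = 0.696). After removal of the GC and length trend the median was -0.366 (95% interval -0.475 to -0.258, camera adjusted p = 3.12e-05), which argues against that trend as the whole cause. A lower share of cycling cells would lower mitosis genes alike. The location of mitosis genes lay 0.333 above that of S phase genes, with a lower 95% limit over genes of 0.157. The donor differences were 0.50, 0.96, -0.21 and 0.07, so donor C goes the other way. In donors A and B MKI67 differed by -2.20 and -1.39 and TOP2A by -0.88 and -1.20, though the mitosis medians there were 0.09 and 0.02. A lower share of cycling cells may still contribute and is left open.

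The number of genes called was 408 in the real split and 0 at most in the 7 other splits that part all 4 donor pairs. The number of lists was 12, against at most 11. Only 1 of 8 splits gave as many in each case, the real one, but 8 splits are too few for a share under 0.05. Splits that part 2 pairs gave at most 0 genes and up to 14 lists. Where these part both donors in the real direction, their difference is that of the treatment in 2 donors, so they do not measure chance. With up to 11 lists in the other splits of all pairs, the count at the preset correlation does not by itself set the treatment apart. In the 7 other splits of all pairs the absolute median reached 0.375 for the interferon-stimulated list and 0.426 for the NF-kB list, below the real 0.64 and 0.59. Each list median had the same sign in all 4 donors, so exchanging any donor was bound to lower it. The real split had to come out largest here, and nothing is concluded from that. Splits that part 2 pairs, whose difference rests on 2 donors, reached 0.853 and 0.724. They include the treatment difference of 2 donors, so no conclusion is drawn from the size of these medians.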

How the results depend on the processing

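Tests with GC and length corrected, annotated genes only and thinned reads were chosen after seeing the data, as was the leave-one-out count on the same genes. The cause was not tested for any change below. The count without donor C rose, so fewer donors do not account for all of these changes. The count of 408 genes became 0 with no replicate block, 698 with array weights and 959 by DESeq2, and 8 to 752 with 1 donor left out. The count of 12 lists became 0 with an estimated correlation and 1 by fry. Without the donor block SLC1A5 was -0.51 and not called, OXPHOS complexes II to V were -0.088 and called, and the block changed the calls of the 24 largest rises and falls and of 2 lists (amino acid, immediate early). Complexes II to V were also called with no filter (-0.088) and after quantile normalization (-0.13). MYC was called with pseudocount 5 (-0.87), the filter of 50 (-0.87), quantile normalization (-0.89), annotated genes only (-0.87), edgeR (-0.89) and DESeq2 (-0.88). It was not called with pseudocount 0.5, no filter, TMM scaling, array weights, GC and length corrected or thinned reads. Nor was it called with no donor block, or without donor A, C or D. MYC targets (-0.19) and complex I (-0.17) lost their call with an estimated correlation, and complex I also by fry (-0.17). Leaving out 1 donor gave -1.17 to -0.66 for MYC, -0.52 to -0.50 for SLC1A5, -0.031 to 0.084 for STAT3, -0.11 to 0.14 for the STAT3 pathway list, -0.26 to -0.12 for complex I and -0.18 to -0.01 for complexes II to V.

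Sign changes touched only results that were not called. STAT3 was -0.038 after quantile normalization. Megakaryocyte and platelet markers were 0.18 with pseudocount 0.5, the LSC17 genes -0.012 with pseudocount 5, and mitosis 0.026 with the filter of 50. With GC and length corrected the medians were 0.004 (TCA cycle), 0.046 (glycolysis), 0.001 (NRF2 targets and pro-apoptotic BCL2 members) and 0.022 (stem and progenitor markers). With 1 donor left out the ranges were -0.083 to 0.029 for glycolysis, -0.069 to 0.025 for NRF2 targets, -0.061 to 0.104 for heat shock, -0.094 to 0.008 for p53 targets, -0.076 to 0.09 for mitosis, -0.019 to 0.091 for autophagy, -0.013 to 0.06 for LSC17, -0.25 to 0.007 for myeloid markers, -0.226 to 0.085 for NK cells and -0.11 to 0.30 for megakaryocytes and platelets. Of 398 alternative values of the 24 largest rises and falls, 302 kept direction and call, 96 lost the call and 0 changed sign.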

Other observations

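Both tests here were chosen after the values had been seen. MAT2A, which makes the methyl donor S-adenosylmethionine, fell to a fold of 0.45 (SE 0.154 on the log2 scale, limma adjusted p = 0.0125, lower in 4 of 4 donors), and the cholesterol exporter ABCA1 rose by 0.98 ± 0.14 (SE, limma adjusted p = 0.0163, higher in 4 of 4 donors). The MAT2A call was lost without donor D (adjusted p = 0.0842) and the ABCA1 call without donor A (0.0637) or B (0.0518). The fatty acid desaturase gene SCD had a difference of -0.85 ± 0.22 (SE, limma adjusted p = 0.0687), and passed by edgeR (adjusted p = 0.04) and DESeq2 (0.00599).

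The fall of CYP1A1 raised the hypothesis that targets of the aryl hydrocarbon receptor fell together. Of 6 other targets measured, 4 were lower and 0 passed, CYP1B1 (-1.43), TIPARP (-0.53) and AHRR (-0.50) among the lower ones. CYP1B1 and TIPARP were lower in 3 of 4 donors and AHRR in 2. Without donor C CYP1B1 (-2.09, limma adjusted p = 0.0108) and TIPARP (-0.87, 0.0097) passed. CYP1B1 ranged from 0 to 22850 normalized counts over the libraries, and its largest difference, -2.98 in donor B, may rest on few reads. CYP1B1 was -0.91 without donor B, and AHRR -0.15 without donor D and -0.78 without donor B, with no call. For this list limma's camera gave adjusted p = 0.47, over the 2 lists tested. The 95% interval over genes of the location was -1.43 to 0.33, which leaves it open. The rise of ABCA1 raised the hypothesis that liver X receptor targets rose together. For the 9 other targets measured the median was 0.08. Limma's camera gave adjusted p = 0.55, with an interval over genes of -0.28 to 0.36, which leaves that open too.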
